A study of Mus musculus with 12 samples.

How the data were processed

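RNA was measured by sequencing in 12 libraries of mouse bone marrow-derived macrophages. Bone marrow was cleared of red blood cells and grown for 6 days in medium with 10% L929-conditioned medium, the usual source of macrophage colony-stimulating factor. The 12 libraries form 4 groups of 3: wild type (WT) and COQ6 D316Y, each unstimulated or after 24 h with 100 ng/mL lipopolysaccharide (LPS). Per the submitters' processing notes, the tools used were bcl2fastq, STAR 2.5.1a, Subread, featureCounts 1.4.6-p5, edgeR and limma; the notes do not say which step each one served. The genome build and gene annotation the authors used are not given in the sources used here. Result files of a pathway program that the notes mention were not used here.

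The authors deposited 2 tables of 12493 entries, and both hold the same log2 counts-per-million values (log2 CPM) of all 12 libraries, with a largest difference of 0 between the tables. Each table also gives the authors' log2 fold change with its limits, their mean log2 expression, and the deposited p-value and adjusted p-value of 1 genotype comparison, per the file headers. The deposited mean expression was not the plain mean of the 12 columns, and the reason is not known from the sources used here. The tables list only part of the genes of the mouse genome, and the authors' rule for leaving genes out is not stated. After 52 repeated gene identifiers were taken once, 12441 genes remained; all 12441 identifiers were found in GENCODE M21 (assembly GRCm38), which gave positions, gene types, lengths and GC content. Symbols of 15 genes that a spreadsheet had turned into dates were restored from their identifiers.

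The log2 values were checked against the form log2 of reads plus 0.5 over an effective library size. In each library, 100% of the values under 200 reads fell within 0.01 of a whole read, which recovered the reads per gene. The reads in the table came to between 32.8 and 47.2 M per library. A gene with 0 reads was given a floor of 3 reads per library, and a fold against such a group is printed only as a bound. Shares of reads carry 95% Wilson intervals, whose half-widths were at most 0.00513 percentage points for mitochondrial reads, 0.00763 for ribosomal protein reads and 0.0109 for Fth1 reads. Reads without molecular identifiers are not independent molecules, so these intervals and floors cover counting error only.

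Because the deposited values are log2 values, each comparison used limma 3.58.1 in R 4.3.3 with data.table version 1.17.8: a linear model per gene, with eBayes moderation (trend and robust). Genes with a group mean of at least 0 log2 CPM in at least 1 of the compared groups were tested. The tests were two-sided with Benjamini-Hochberg adjustment over the genes tested, a threshold of 0.05 and no fold minimum. D316Y was compared with WT within the 6 unstimulated and within the 6 LPS libraries. The LPS comparisons and the interaction (the genotype difference under LPS minus that without it) came from 1 fit of 4 groups. "Passed" means adjusted p under 0.05.

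The 35 gene lists, with 828 members in all, covered mitochondrial and lipid metabolism, stress responses, inflammation and macrophage functions, markers of other bone marrow cells, and sex-linked genes. Lists with at least 5 measured members were tested with camera of limma (preset correlation between genes 0.01), which compares a list with the other genes, with Benjamini-Hochberg adjustment over the lists of a comparison. Beside it stand camera with an estimated correlation and fry, which tests whether a list's genes move, on balance, in 1 direction. Members past 0.05 were counted over all genes tested and adjusted over the list alone.

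The genes named follow a rule. In each comparison it takes Coq6; then, among genes that passed, had a mean of at least 1 log2 CPM in a group, did not overlap between the groups' libraries and had no predicted, clone or pseudogene name, the 12 largest rises and 12 largest falls (10 and 10 for LPS and the interaction); then up to 4 members of each list with the smallest adjusted p. Where fewer than 6 genes passed in a direction, those with the smallest unadjusted p filled up to 6 and are said not to pass, and a list with no member past 0.05 gives up to 2. Of these, a selection is printed. The comparisons, tests, lists, named-gene rule and most alternatives were set before the data were examined; the exceptions are stated.

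Nothing in the labels says that replicates came from separate animals or cultures, so the p-values measure only the spread between these samples. Pairing was checked as the correlation across genes of deviations from the group mean, between libraries of the same number. It was 0.660, 0.636 and 0.203 between unstimulated WT and D316Y, so values with the replicate number as a block are given beside that comparison where they change a count or a call. It was -0.159, 0.0940 and -0.0189 between the LPS groups, 0.373, 0.200 and -0.0510 between WT without and with LPS, and -0.181, -0.224 and -0.0680 in D316Y, so these were left unpaired.

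The tests were also run on simulated data with the spread of the real groups. Of 100 genes changed by 1 on the log2 scale, 50 passed in the unstimulated comparison, 59 under LPS and 33 in the interaction; of 100 changed by 2, the counts were 95, 96 and 80. Of the unchanged genes, 9 of 11298, 11 of 11056 and 3 of 11693 passed. Of 6 changed lists, 6 were recovered in each comparison, and of 20 unchanged lists at most 1 was called. The simulated genes were drawn independently of each other and the lists at random, so these counts do not cover lists whose genes move together. In the real data, as given below, regrouping the unstimulated libraries called up to 17 lists.

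The alternatives were libraries centred on their median, quantile normalization, no filter or a stricter one (group mean of at least 3 log2 CPM), eBayes without trend and robust, array weights, the replicate block, all 12 libraries in 1 fit, a minimum fold of 2, and leaving out each library in turn. Chosen after the data were seen were voom with quality weights (limma) on the recovered reads, both unstimulated replicate 1 libraries left out, the mitochondrial share as a covariate, and a length and GC trend removed from each library. A pseudocount does not apply to values deposited as log2.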

Results

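Macrophages grown from the bone marrow of WT mice and of mice homozygous for D316Y in COQ6, a flavin-dependent monooxygenase of coenzyme Q biosynthesis in mitochondria, were profiled at rest and after LPS, the bacterial cell wall lipid that activates macrophages through Toll-like receptor 4. Each of the 4 groups had 3 libraries. The reads in the table came to 46.9, 36.9 and 32.8 M in unstimulated WT replicates 1, 2 and 3 and 42.2, 42.0 and 37.6 M in unstimulated D316Y. With LPS they came to 47.2, 46.1 and 46.6 M in WT and 41.1, 42.6 and 35.3 M in D316Y. LPS separated the libraries along the first principal component, which held 76.0% of the variance.

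The unstimulated replicate 1 libraries of both genotypes stood apart from replicates 2 and 3. Mitochondrially encoded genes took 0.449% of the reads of WT replicate 1 and 0.949% of D316Y replicate 1, against 2.15% and 1.97% in WT and 2.97% and 2.21% in D316Y replicates 2 and 3. Ribosomal protein genes took 2.68% and 3.72% of the reads in the replicate 1 libraries and between 5.21% and 6.48% in the other unstimulated libraries. With LPS the mitochondrial share lay between 0.658% and 1.10%.

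**Figure D1:**
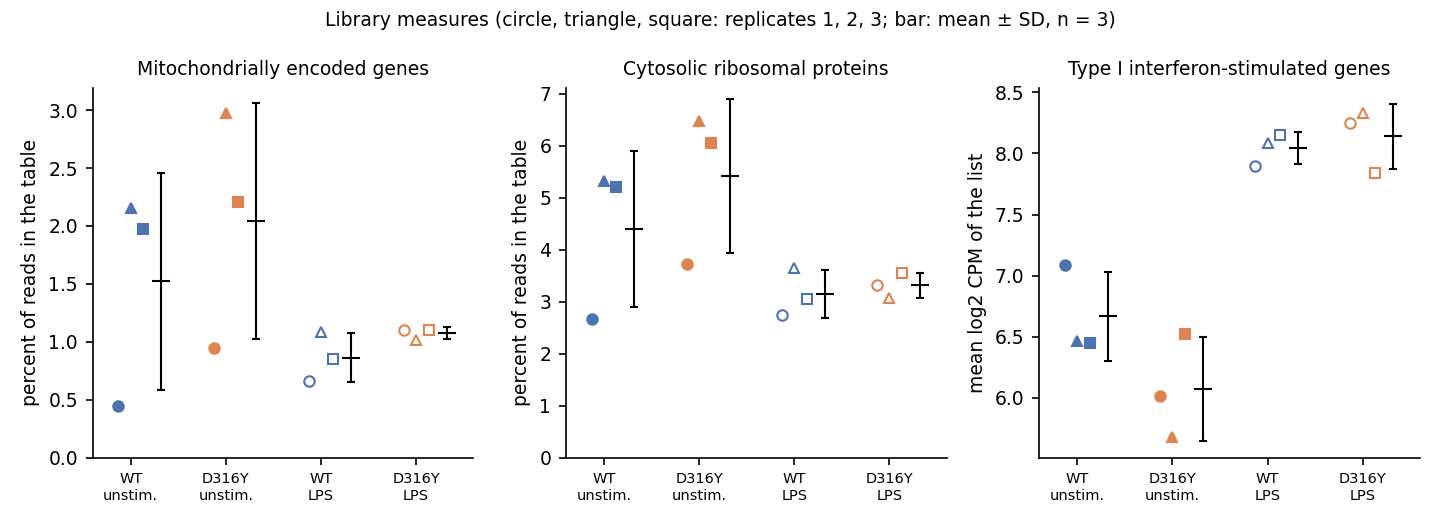
Share of reads from mitochondrially encoded genes (%), share from cytosolic ribosomal protein genes (%) and mean log2 CPM of the type I interferon-stimulated gene list, 1 point per library and 3 libraries per group. In the unstimulated groups the replicate 1 libraries have the lowest mitochondrial shares, 0.449% in WT and 0.949% in D316Y.

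Coq6 itself was expressed in every library and passed in no comparison. Its mean was 3.49 ± 0.04 log2 CPM (SD, n = 3) in unstimulated WT, 3.56 ± 0.17 in unstimulated D316Y, 3.57 ± 0.14 in WT with LPS and 3.58 ± 0.21 in D316Y with LPS. Coq6 (ENSMUSG00000021235) lies on chromosome 12 at 84361657 to 84373796 of GRCm38. It drew 640, 533 and 448 reads in unstimulated WT, 683, 571 and 590 in unstimulated D316Y, 455, 476 and 518 in WT with LPS, and 511, 401 and 376 in D316Y with LPS. The D316Y minus WT difference was 0.07 on the log2 scale without LPS (SE 0.15, limma adjusted p 0.953) and 0.02 with LPS (SE 0.16, adjusted p 0.995). LPS changed it by 0.08 in WT (SE 0.15, adjusted p 0.706) and by 0.03 in D316Y (SE 0.15, adjusted p 0.913). No gene within 10 Mb of Coq6 passed in either genotype comparison, 0 of 95 tested without LPS and 0 of 90 with LPS (limma). Of these neighbors, 1.05% and 4.44% had an unadjusted p under 0.05, against 2.94% and 6.52% of all other genes (Fisher's exact test, two-sided, p 0.531 and 0.664).

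The first comparison asked how D316Y macrophages differ from WT macrophages at rest. Rab4a, which encodes a small GTPase that recycles endocytosed receptors to the cell surface, was 4.65-fold lower in D316Y. It fell by 2.22 on the log2 scale (SE 0.21, adjusted p 0.0497), from 3.95 ± 0.07 to 1.73 ± 0.37 log2 CPM (SD, n = 3), with 913, 718 and 613 reads in WT and 232, 158 and 140 in D316Y. It was the 1 gene of 11525 tested that passed, and 337 genes had an unadjusted p under 0.05. Rab4a lies on chromosome 8 at 123805985 to 123835287. Its call sat close to the threshold: the adjusted p was 0.0848, 0.388 and 0.514 without WT replicate 1, 2 and 3, and 0.156 and 0.208 without D316Y replicate 2 and 3.

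Blocking on the replicate number raised the count to 6 genes, with 2119 at an unadjusted p under 0.05. Beside Rab4a (adjusted p 0.00439 with the block) these included Ide, the insulin-degrading metalloprotease (-1.60, SE 0.24, adjusted p 0.390 without and 0.00304 with the block), and Dhcr7, the reductase that completes cholesterol synthesis (1.42, SE 0.26, adjusted p 0.942 and 0.00953). The others were the RNA gene G530011O06Rik (-2.50, SE 0.29, adjusted p 0.125 and 0.0114), the transcription factor Zbtb20 (1.03, adjusted p 0.0221 with the block) and Ubn2 (1.07, adjusted p 0.0371 with the block). Zbtb20, Ubn2 and G530011O06Rik were chosen after their values were seen. Ifi208, an interferon-inducible gene of the Ifi200 family of nucleic acid sensors, differed the most among genes named here without passing: 3.66 on the log2 scale (SE 0.51, adjusted p 0.314, 0.0525 with the block), from 25, 19 and 17 reads in WT to 260, 145 and 597 in D316Y. Other genes that had small unadjusted p without passing were Zfp704 (0.86), Dppa3 (1.17), Psd3 (0.95) and Lpp (0.57), higher in D316Y, and Cnbd2 (-0.95), the nucleotide receptor P2ry2 (-0.59), the basement membrane collagen Col18a1 (-0.98) and the histone demethylase Phf2 (-0.88), lower.

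**Figure D2:**
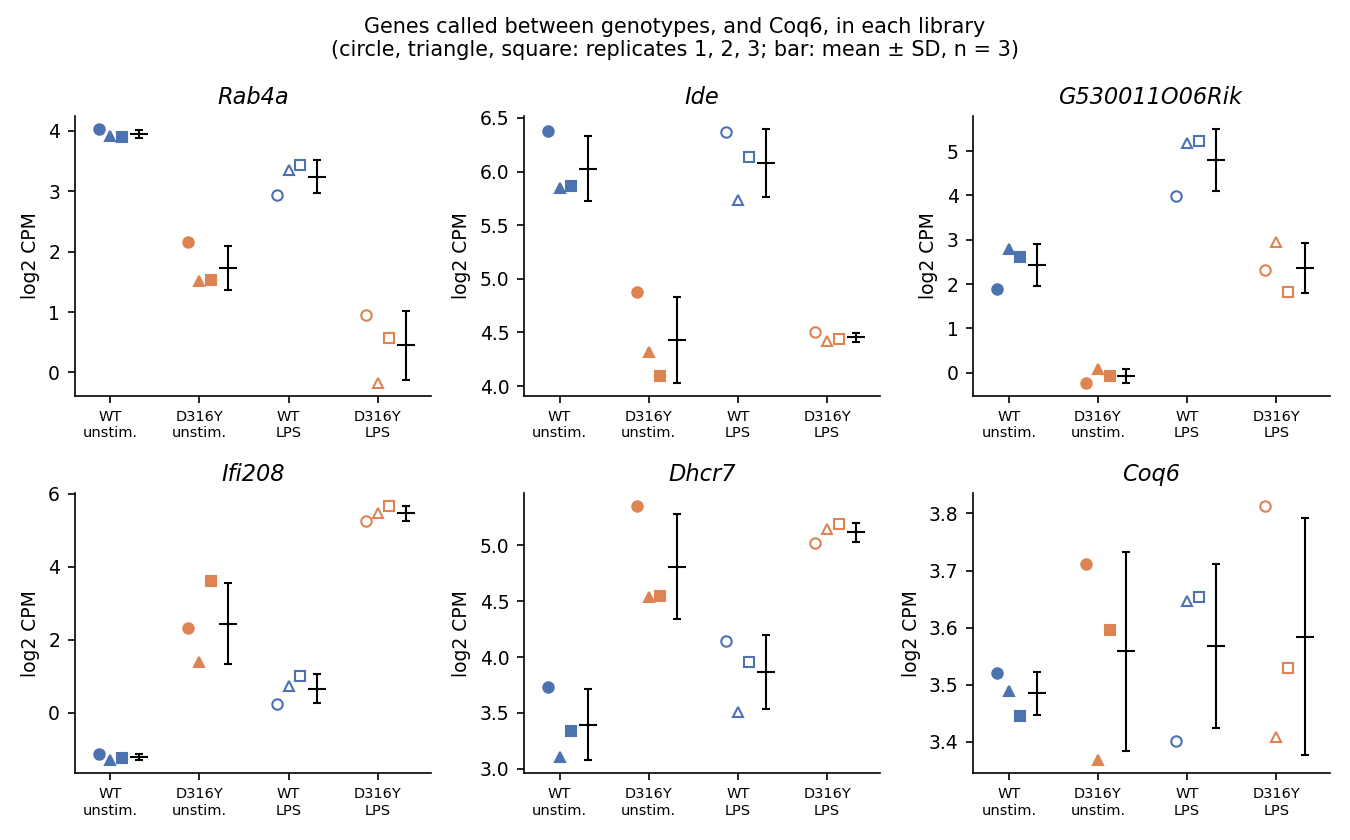
Level of Rab4a, Ide, G530011O06Rik, Ifi208, Dhcr7 and Coq6 in each library (log2 CPM), by group; circle, triangle and square are replicates 1, 2 and 3, and the bar is the mean ± SD (n = 3). Rab4a averages 3.95 and 1.73 in unstimulated WT and D316Y and 3.24 and 0.45 with LPS, while Coq6 lies between 3.49 and 3.58 in every group.

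Interferon and inflammatory gene lists stood lower in resting D316Y cells. All 38 type I interferon-stimulated genes had negative differences, with a median of -0.60 on the log2 scale (camera adjusted p 5.05e-17; p = 0.117 with an estimated correlation). Among them were Cmpk2, a mitochondrial nucleotide kinase (-1.02), and Oas1g, a sensor of double-stranded RNA (-0.64). The list mean was 7.09, 6.47 and 6.45 log2 CPM in WT replicates 1, 2 and 3 and 6.02, 5.68 and 6.53 in D316Y, so D316Y replicate 3 lay within the WT values. Of the integrated stress response genes, the targets of ATF4 and their partners, 21 of 23 were lower (median -0.35, adjusted p 1.75e-05; p = 0.0829 with an estimated correlation). The glutathione-degrading Chac1 stood at -0.97 and the pseudokinase Trib3 at -0.71. Antigen presentation genes were lower in 16 of 23 (median -0.33, adjusted p 0.00150; p = 0.228 with an estimated correlation). The peptide transporter Tap1 stood at -0.70 and the class I molecule H2-Q6 at -0.78. These 3 lists passed camera whichever single library was left out. Without WT replicate 1 the median was -0.38 for the interferon-stimulated genes and -0.18 for antigen presentation, and without D316Y replicate 2 it was -0.21 for the integrated stress response and -0.20 for antigen presentation.

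Inflammatory cytokine and chemokine genes were lower in 15 of 18 (median -0.23, adjusted p 0.0108; p = 0.195 with an estimated correlation), with Il10 at -0.51 and Cxcl10 at -0.79. Their adjusted p was 0.0850 without WT replicate 2, 0.0961 without WT replicate 3, 0.138 without D316Y replicate 1 and 0.0620 without D316Y replicate 2. Inflammatory effector and NF-kB feedback genes were lower in 23 of 29 (median -0.25, adjusted p 0.00100; p = 0.143 with an estimated correlation), with the costimulatory receptor Cd40 at -0.55 and the GTPase Gbp2 at -0.77. Their adjusted p was 0.0639 without D316Y replicate 1, and the median -0.11 without WT replicate 1 and -0.17 without D316Y replicate 2. Lysosome and phagocytosis genes were lower in 27 of 30 (median -0.20, adjusted p 0.00436; p = 0.410 with an estimated correlation). Tfeb, the master regulator of lysosome genes, stood at -0.37 and the lysosomal calcium channel Mcoln1 at -0.32. Here the median was -0.05 without WT replicate 1, -0.10 without D316Y replicate 2 and -0.12 without D316Y replicate 3, with adjusted p 0.370, 0.115 and 0.144, and it was -0.31 without WT replicate 2 and -0.35 without D316Y replicate 1.

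Mitochondrially encoded genes and ribosomal protein genes stood higher in resting D316Y cells, and both moved with the replicate 1 libraries described above. All 13 mitochondrially encoded genes had positive differences (median 0.60, adjusted p 0.00159; p = 0.350 with an estimated correlation), with the complex I subunits mt-Nd3 at 0.84 and mt-Nd4l at 0.77. The median was -0.15 without WT replicate 1, 0.29 (adjusted p 0.0889) without D316Y replicate 2, and 0.98, 0.97 and 1.05 without WT replicate 2, WT replicate 3 and D316Y replicate 1. Cytosolic ribosomal protein genes were higher in 47 of 48 (median 0.24, adjusted p 1.75e-05; p = 0.415 with an estimated correlation), with Rpl24 at 0.67 and Rps24 at 0.73. Their median was -0.02 without WT replicate 1, 0.38 without WT replicate 2 or 3, and 0.46, 0.11 and 0.16 without D316Y replicates 1, 2 and 3. Within the replicate pairs 1, 2 and 3 the list means were higher in D316Y by 1.26, 0.49 and 0.14 for mitochondrially encoded and by 0.44, 0.23 and 0.15 for ribosomal protein genes. In alternatives chosen after the data were seen, the medians were 0.30 (adjusted p 3.60e-07) and 0.18 (adjusted p 1.25e-12) without both replicate 1 libraries, and 0.03 for ribosomal protein genes with the mitochondrial share as a covariate (adjusted p 0.139).

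In these 8 lists, 0 members passed over all genes (limma) and 0 adjusted over the list alone. With an estimated correlation 0 lists passed, and fry called 0. With the replicate block 13 lists were called, which adds complex I (median 0.10, adjusted p 0.00464 with the block), complexes III to V (0.12, 0.00492), tricarboxylic acid cycle (-0.11, 0.0153), glycolysis (-0.11, 0.0153) and macrophage identity genes (-0.14, 0.0150). Without the block these 5 were called when D316Y replicate 1 was left out (0.21, 0.23, -0.29, -0.35 and -0.20) or WT replicate 2 was (0.16, 0.20, -0.19, -0.22 and -0.22), and complex I, complexes III to V and macrophage identity genes without WT replicate 3 (0.15, 0.20 and -0.22). Over all alternatives their medians ran from -0.04 to 0.21, -0.06 to 0.23, -0.29 to 0.02, -0.35 to 0.01 and -0.22 to -0.01. They were called in 5, 6, 4, 4 and 5 of the 13 alternatives. The genes closest to the COQ6 reaction were not called. Of 15 coenzyme Q biosynthesis genes 7 were higher and 8 lower (median -0.02, adjusted p 0.683), with the atypical kinase Coq8b at -0.40 and the prenyltransferase Coq2 at -0.35. The quinone-linked dehydrogenases, which pass electrons to coenzyme Q, had a median of -0.01 over 14 genes (adjusted p 0.80), and their mean was 0.01. NRF2 and glutathione genes had a median of -0.03 (mean 0.03, adjusted p 0.751), with the cystine transporter Slc7a11 at 0.83. Marker lists of neutrophils (median 0.34), monocytes and progenitors (-0.31), dendritic cells (0.09) and osteoclasts (0.14) were not called either, with adjusted p from 0.358 to 0.506. The neutrophil list was called without D316Y replicate 2 (0.64, adjusted p 0.0406), and its median ran from -0.11 to 0.64 over the alternatives. Among their members, S100a8 and S100a9, calcium-binding proteins of neutrophils and monocytes, stood at 1.18 and 1.10, and the progenitor receptor Kit at -1.23.

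The second comparison asked how the genotypes differ once activated by LPS. Ifi208 rose 27.9-fold in D316Y, by 4.80 on the log2 scale (SE 0.21, adjusted p 5.61e-07), from 50, 63 and 83 reads in WT to 1395, 1671 and 1650 in D316Y. Dhcr7 rose 2.38-fold (1.25, SE 0.17, adjusted p 0.0239), from 3.87 ± 0.33 to 5.12 ± 0.09 log2 CPM (SD, n = 3). Rab4a was 6.93-fold lower (-2.79, SE 0.29, adjusted p 0.00205), Ide 3.08-fold lower (-1.62, SE 0.16, adjusted p 0.00158) and G530011O06Rik 5.42-fold lower (-2.44, SE 0.33, adjusted p 0.0239). These 5 were the genes that passed of 11306 tested, and 735 had an unadjusted p under 0.05.

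Ide lies on chromosome 19 at 37268743 to 37337852, Dhcr7 on chromosome 7 at 143823145 to 143848410, Ifi208 on chromosome 1 at 173673675 to 173698395 and G530011O06Rik on chromosome X at 169975043 to 169978917. Other Ifi200-family genes had small differences with LPS, among them Ifi206 (0.25), Ifi209 (0.13), Ifi213 (0.22), Ifi204 (0.06) and Ifi205 (0.25), and negative ones without it (-0.96, -0.63, -0.75, -0.52 and -0.48); 0 of them passed (limma), and they were chosen after their values were seen. Ifi208 and Ide passed whichever single library was left out. Rab4a had an adjusted p of 0.0535 without WT replicate 3. Dhcr7 had 0.192 without WT replicate 3 and 0.0913, 0.25 and 0.303 without D316Y replicate 1, 2 and 3; G530011O06Rik had 0.177 and 0.308 without WT replicate 2 and 3 and 0.0913 and 0.277 without D316Y replicate 1 and 3. The count was 22 without WT replicate 2, 2 without WT replicate 3, and 3 without D316Y replicate 1 or 3.

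Genes with small unadjusted p that did not pass included Zfp263 (0.78, adjusted p 0.111), Zc3h7a (0.71), the elongation factor subunit Ccnt2 (0.69) and Fnbp4 (0.73), higher in D316Y, and Cnbd2 (-1.43, adjusted p 0.212), the lysosomal protein Plbd2 (-0.65), the cytokine receptor Crlf2 (-0.74) and the adhesion molecule Nectin2 (-0.64), lower.

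By list, 7 were called under LPS, 2 higher and 5 lower in D316Y, all with medians under 0.3 in size. Mitochondrially encoded genes were higher in 12 of 12 (median 0.26, adjusted p 0.00597; p = 0.299 with an estimated correlation), such as mt-Nd5 (0.32) and mt-Co1 (0.34). The mitochondrial share was 1.10%, 1.02% and 1.10% in D316Y against 0.658%, 1.08% and 0.849% in WT. Inflammatory cytokine and chemokine genes were higher in 18 of 27 (median 0.15, adjusted p 0.0375; p = 0.331 with an estimated correlation), with the neutrophil chemokine Cxcl2 at 0.45 and the interleukin-12 subunit Il12a at 0.88. Tricarboxylic acid cycle genes were lower in 20 of 21 (median -0.13, adjusted p 0.00682; p = 0.305 with an estimated correlation), with the fumarase Fh1 at -0.22 and the malate dehydrogenase Mdh2 at -0.19. Glycolysis and hypoxia genes were lower in 26 of 32 (median -0.19, adjusted p 0.0259; p = 0.498 with an estimated correlation), with the prolyl hydroxylase P4ha2 at -0.69 and, against that direction, the enolase Eno2 at 0.77. Mevalonate and cholesterol synthesis genes were lower in 22 of 24 (median -0.17, adjusted p 0.00751; p = 0.308 with an estimated correlation), opposite to Dhcr7, the 1 member that passed over all genes and the 1 adjusted over the list alone.

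Lysosome and phagocytosis genes were lower in 26 of 30 (median -0.15, adjusted p 0.00682; p = 0.263 with an estimated correlation), with the membrane protein Lamp1 at -0.46. Cell cycle genes were lower in 36 of 44 (median -0.13, adjusted p 0.0277; p = 0.416 with an estimated correlation), with the helicase subunits Mcm3 at -0.36 and Mcm6 at -0.34. Apart from Dhcr7, 0 members of these 7 lists passed over all genes (limma) or adjusted over the list alone; 0 lists passed with an estimated correlation, and fry called 0. The 7 lists rested on single libraries. Without WT replicate 1 their adjusted p lay at 0.567 (mitochondrially encoded, median 0.07), 0.812 (cytokines, -0.01), 0.567 (tricarboxylic acid cycle, -0.05), 0.754 (glycolysis, 0.0025), 0.0866 (cholesterol, -0.14), 0.0539 (lysosome, -0.11) and 0.353 (cell cycle, -0.08), so none of the 7 was called. Without D316Y replicate 1 the medians were 0.04 for cytokines, -0.08 for tricarboxylic acid cycle, -0.13 for glycolysis, -0.09 for cholesterol and -0.03 for cell cycle genes, and these 5 were not called. Other changes were 0.21 for mitochondrially encoded genes without WT replicate 3 (adjusted p 0.0917), -0.09 for lysosome genes without D316Y replicate 3 (0.128), and -0.15 for glycolysis (0.143), 0.05 for cytokine (0.216) and -0.06 for cell cycle genes (0.143) without D316Y replicate 2. Without WT replicate 2 the medians were 0.47 for mitochondrially encoded, -0.23 for tricarboxylic acid cycle, -0.33 for glycolysis and -0.09 for cell cycle genes (the last with adjusted p 0.115), and without D316Y replicate 3 they were 0.26 for cytokine and -0.26 for cell cycle genes.

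Under LPS the type I interferon-stimulated genes were higher in 27 of 38 and lower in 11 (median 0.09, adjusted p 0.0538), with the antiviral genes Oas2 at 0.71 and Mx2 at 0.60; over all genes 0 members passed (limma), and adjusted over the list alone 1 did, Oas2. The list was called higher without WT replicate 2 (0.11, adjusted p 0.0439), WT replicate 3 (0.14, adjusted p 0.0130) or D316Y replicate 3 (0.20, adjusted p 5.41e-09), and with the alternatives its median ran from -0.05 to 0.20. Of the inflammatory effectors the scavenger receptor Marco (-0.66) was the 1 that passed adjusted over the list alone. Coenzyme Q biosynthesis genes had a median of 0.02 (mean -0.02, adjusted p 0.988) and quinone-linked dehydrogenases of -0.07 (adjusted p 0.390), with the proline dehydrogenase Prodh at 0.61. Complex I and complexes III to V both had a median of -0.02 (adjusted p 0.390 and 0.384). Both were called lower without WT replicate 1 (-0.13 each, adjusted p 0.000126 and 3.50e-05) and higher without WT replicate 2 (0.11 each, adjusted p 0.0114 and 0.00755).

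**Figure D3:**
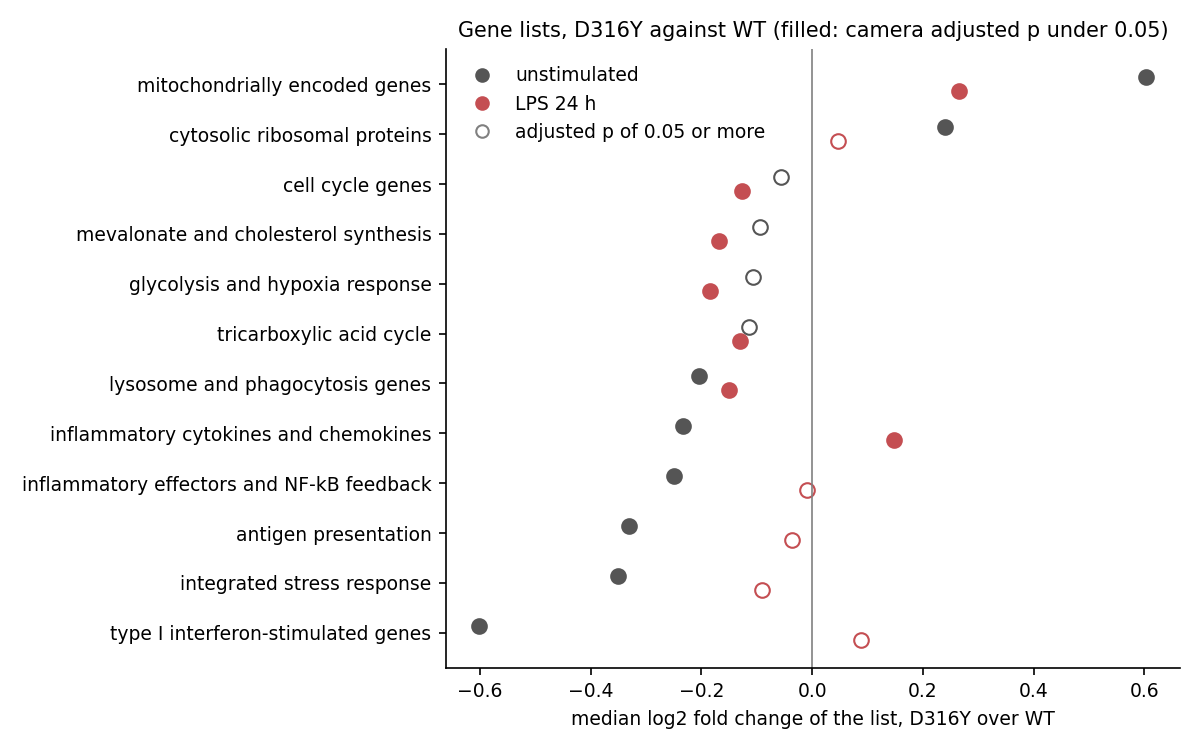
Median log2 fold change of D316Y over WT for 12 gene lists, without LPS (grey) and with LPS (red); filled points are lists with a camera adjusted p under 0.05. The type I interferon-stimulated genes lie at -0.60 without LPS and at 0.09 with LPS.

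The genotype differences with and without LPS went partly together. Across 10913 genes tested in both, Pearson's r of the log2 differences was 0.435 and Spearman's rho 0.374, and 64.0% of genes had the same sign; genes are not independent replicates. Rab4a passed in both comparisons, where 0.000275 genes were expected by chance (Fisher's exact test, p 0.000275). That count takes the 2 comparisons as independent, which they may not be. The labels do not say whether libraries of 1 number with and without LPS share an animal. Ide, Dhcr7 and G530011O06Rik had differences of the same sign and similar size in both conditions, at -1.60 and -1.62, 1.42 and 1.25, and -2.50 and -2.44.

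The interaction asked whether the genotype difference itself depends on LPS. No gene passed: limma called 0 of 11918, with 251 at an unadjusted p under 0.05, and 0 with array weights (1468 at that p) or voom with quality weights (686). For Coq6 it was -0.06 (SE 0.21, adjusted p 0.999). The genes with the smallest unadjusted p did not pass (limma adjusted p 0.999). On the side of a higher difference with LPS they were P2ry2 (0.70), the NOD-pathway kinase Ripk2 (0.80), the antiviral Slfn4 (1.44) and the anticoagulant receptor Thbd (0.93). On the other side they were Wfdc21 (-1.79), the kinase Grk5 (-1.02) and the interleukin-12 subunit Il12b (-2.20). Wfdc21 had 2, 6 and 2 resting reads in WT and 11, 11 and 14 in D316Y, so its value rests on few reads.

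By list, 8 differed in the interaction by camera, and 0 of their members passed, over all genes or adjusted over the list alone. The type I interferon-stimulated genes, lower in D316Y at rest and not with LPS, had positive interaction values in 38 of 38 (median 0.68, adjusted p 1.27e-22; p = 0.0444 with an estimated correlation, adjusted p 0.817), with the transcription factor Stat2 at 0.80 and Ifit2 at 1.16. Antigen presentation genes followed (median 0.24, adjusted p 0.000458; p = 0.149 with an estimated correlation), with the class I transactivator Nlrc5 at 0.68. Both lists passed whichever single library was left out, with medians of 0.44 and 0.14 without unstimulated D316Y replicate 2, and with antigen presentation at 0.07 without unstimulated WT replicate 1 (adjusted p 0.0499) and 0.37 without WT replicate 2. The integrated stress response list had a median of 0.27 (adjusted p 0.00417; p = 0.0976 with an estimated correlation), with Chac1 at 1.10 and Trib3 at 0.94, and was not called without unstimulated D316Y replicate 2 (0.14, adjusted p 0.116). With an estimated correlation 0 lists passed after adjustment, and fry called 0. Lists were called as often when the same libraries were split in other ways: at least 8 lists in 68 of 100 splits, the real one included.

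The LPS comparisons describe the activation that the genotype differences are read against. In WT, 4328 of 11663 genes passed, 2114 up and 2214 down, and 2207 of them by at least 2-fold (1012 up, 1195 down). In D316Y, 4524 of 11795 passed, 2287 up and 2237 down, and 2333 by at least 2-fold (1106 up, 1227 down). The acute-phase protein gene Saa3 rose the most among genes with reads in every library, by 13.97 on the log2 scale in WT (SE 0.22, adjusted p 8.27e-14) and 14.19 in D316Y (SE 0.22, adjusted p 6.02e-14). Saa1 had 0 reads in all unstimulated libraries and was at least 2634-fold higher with LPS in WT and at least 2493-fold higher in D316Y; Saa2 was at least 100.4-fold and 88.5-fold higher, and the interleukin-23 receptor gene Il23r at least 229.6-fold and 238.4-fold, against a floor of 3 reads per library.

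Other strong rises in both genotypes were those of Cd38, an NAD-consuming ectoenzyme (9.80 in WT, 10.32 in D316Y), the iron-binding Lcn2 (9.33 and 9.76) and haptoglobin, Hp (8.37 and 8.36). The nitric oxide synthase Nos2 rose by 9.97 (SE 0.82) in WT from 6, 0 and 4 reads, and the interleukin-1 gene Il1a by 9.72 in D316Y from 0, 20 and 3 reads, so both folds rest on few resting reads. Large falls included those of the orphan receptor Gprc5c (-7.74 in WT, -7.05 in D316Y), the organic anion transporter Slco2b1 (-7.26 and -7.52) and the immunoglobulin heavy chain Ighm (-6.94 and -7.22). In WT they also included the lectin Mgl2 (-7.13) and the lipase inhibitor Angptl4 (-7.07). Apart from Ighm these folds rest on few reads with LPS, such as 11, 2 and 1 for Gprc5c in WT. Others passed on too few reads to be given a fold: Tox2, with 0, 0 and 4 LPS reads in WT and 0, 0 and 1 in D316Y, and in D316Y Mgl2 (1, 1 and 0) and Mn1 (2, 0 and 0). The growth factor homolog Fgf13 and the phosphodiesterase Pde1c had 0 reads in all LPS libraries and were at least 46.1-fold and 25.5-fold lower in WT and at least 41.4-fold and 24.0-fold lower in D316Y.

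Inflammatory genes rose together. Of 27 cytokine and chemokine genes 23 rose in each genotype and 1 fell, over all genes and adjusted over the list alone (medians 2.35 in WT and 2.44 in D316Y, adjusted p 8.67e-12 and 1.18e-12; p = 0.00697 and 0.00572 with an estimated correlation, which adjusted were 0.101 and 0.0829 and so did not pass). Il1b rose by 8.20 in WT and 8.91 in D316Y, and the chemokines Ccl5 by 7.94 and 8.43 and Cxcl3 by 5.84 and 5.62. Cxcl3 rose from few resting reads, 5, 8 and 4 in WT and 7, 13 and 9 in D316Y. Of 34 inflammatory effector and NF-kB feedback genes 26 rose in each genotype, and 4 fell in WT and 2 in D316Y, with the same counts adjusted over the list alone (medians 1.31 and 1.5, adjusted p 5.01e-12 and 9.57e-14; p = 0.00655 and 0.00469 with an estimated correlation, adjusted 0.101 and 0.0829). Acod1, which makes itaconate, rose by 7.59 and 8.05, the arginase Arg2 by 5.56 and 5.43 and the prostaglandin E synthase Ptges by 6.25 and 5.99. Of 38 type I interferon-stimulated genes 31 rose in WT and 37 in D316Y, and 33 and 38 adjusted over the list alone (medians 1.12 and 1.93, adjusted p 8.67e-12 and 2.56e-18; p = 0.132 and 0.0664 with an estimated correlation). The regulator Irf7 rose by 2.85 in WT and 3.63 in D316Y, and the nucleic acid sensor Zbp1 by 2.43 and 3.24. Antigen presentation genes were called in D316Y (median 1.13, 15 up and 7 down of 24, adjusted p 0.0412; p = 0.371 with an estimated correlation) and not in WT (0.74, adjusted p 0.187). The call in D316Y was lost without unstimulated replicate 2 or 3 (adjusted p 0.0522 and 0.0815) or LPS replicate 1 or 2 (0.0608 and 0.0524), and WT was called without unstimulated replicate 1 (0.98, adjusted p 0.0389). The class I gene H2-Q7 rose by 3.90 in WT and 4.31 in D316Y, while the class II gene H2-Aa fell (-2.36 and -2.35).

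Lists of glycolysis, nuclear respiratory chain and cholesterol synthesis genes were called higher by camera, calls that were lost with an estimated correlation, and other energy metabolism lists were not called. Of 32 glycolysis and hypoxia genes 24 rose and 2 fell in WT, and 23 rose and 2 fell in D316Y, with 25 up and 2 down adjusted over the list alone in each (medians 1.25 and 1.23, adjusted p 3.04e-09 and 3.17e-08; p = 0.0981 and 0.117 with an estimated correlation). Among them were the lactate exporter Slc16a3 (3.35 and 3.76) and the phosphofructokinase activator Pfkfb3 (3.43 and 3.87). Of 36 complex I genes 26 rose in WT and 20 in D316Y, and 29 and 25 adjusted over the list alone (medians 0.64 and 0.57, adjusted p 2.15e-08 and 7.86e-06; p = 0.102 and 0.171 with an estimated correlation), such as Ndufs3 (0.93 and 1.04). Of 35 genes of complexes III to V 26 and 17 rose, and 30 and 18 adjusted over the list alone (medians 0.82 and 0.62, adjusted p 1.96e-08 and 6.82e-06; p = 0.111 and 0.179 with an estimated correlation), such as the cytochrome oxidase subunit Cox5a (1.18 and 1.49). Of 24 cholesterol synthesis genes 10 rose in each genotype, over all genes and adjusted over the list alone (medians 0.45 and 0.29, adjusted p 0.000505 and 0.00519; p = 0.299 and 0.381 with an estimated correlation), such as the decarboxylase Mvd (1.82 and 1.92). In D316Y the median was 0.20 (adjusted p 0.0582) without unstimulated replicate 3, and 0.48 and 0.44 without unstimulated and LPS replicate 1. Of the mitochondrially encoded genes 0 passed in WT and 1 of 13 fell in D316Y (medians -0.25 and -0.61, adjusted p 0.608 and 0.233). That list was called lower without unstimulated WT replicate 1 (-0.98, adjusted p 0.00367) and without unstimulated D316Y replicate 1 (-1.05, adjusted p 0.0301). Of 23 fatty acid oxidation genes 5 rose and 3 fell in WT and 5 and 5 in D316Y (medians -0.12 and -0.16, adjusted p 0.853 and 0.730). Of 21 tricarboxylic acid cycle genes 4 rose and 2 fell in WT and 4 and 1 in D316Y (medians 0.18 and 0.13, adjusted p 0.264 and 0.345), and the list was called in D316Y without unstimulated replicate 1 (0.30, adjusted p 0.0301).

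Proliferation and alternative activation genes fell. Of 46 cell cycle genes 44 fell in each genotype, over all genes and adjusted over the list alone, where 1 also rose in WT and 2 in D316Y (medians -1.81 and -1.90, adjusted p 6.82e-20 and 5.85e-20; p = 0.0267 and 0.0265 with an estimated correlation, adjusted 0.193 and 0.192), with the cytokinesis motor Kif23 at -2.92 and -3.40 and the cyclin Ccnb2 at -2.76 and -2.83. Of 17 alternative activation genes 12 fell and 3 rose in each, over all genes and adjusted over the list alone (medians -3.19 and -3.17, adjusted p 6.77e-05 and 0.000124; p = 0.0113 and 0.0132 with an estimated correlation, adjusted 0.109 and 0.127), with the lipid-sensing receptor Pparg at -5.40 and -5.20 and the lectin Clec10a at -5.19 and -5.25. Of 8 osteoclast markers 6 fell and 1 rose in each (medians -2.41 and -2.34, adjusted p 0.0447 and 0.0174; p = 0.128 and 0.0862 with an estimated correlation), with the cell fusion gene Dcstamp at -6.01 and -6.23. In WT the adjusted p was 0.0635 and 0.0590 without unstimulated replicate 2 and 3. Neutrophil markers were called higher in WT (median 0.96, 4 of 8 up and 1 down, adjusted p 0.0168; p = 0.0804 with an estimated correlation), through genes such as Lcn2 and Camp (5.18) that activated macrophages also express, and not in D316Y (0.65, adjusted p 0.122). In WT without unstimulated replicate 3 the median was 0.48 (camera adjusted p 0.0939). In D316Y the list was called without unstimulated replicate 1 (1.03, adjusted p 0.0364) or 3 (1.09, adjusted p 0.0359). Camp had 4, 11 and 4 resting reads in WT, so its fold rests on few reads. With an estimated correlation 0 of the lists passed after adjustment in either genotype, and fry called 22 in WT and 18 in D316Y.

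**Figure D4:**
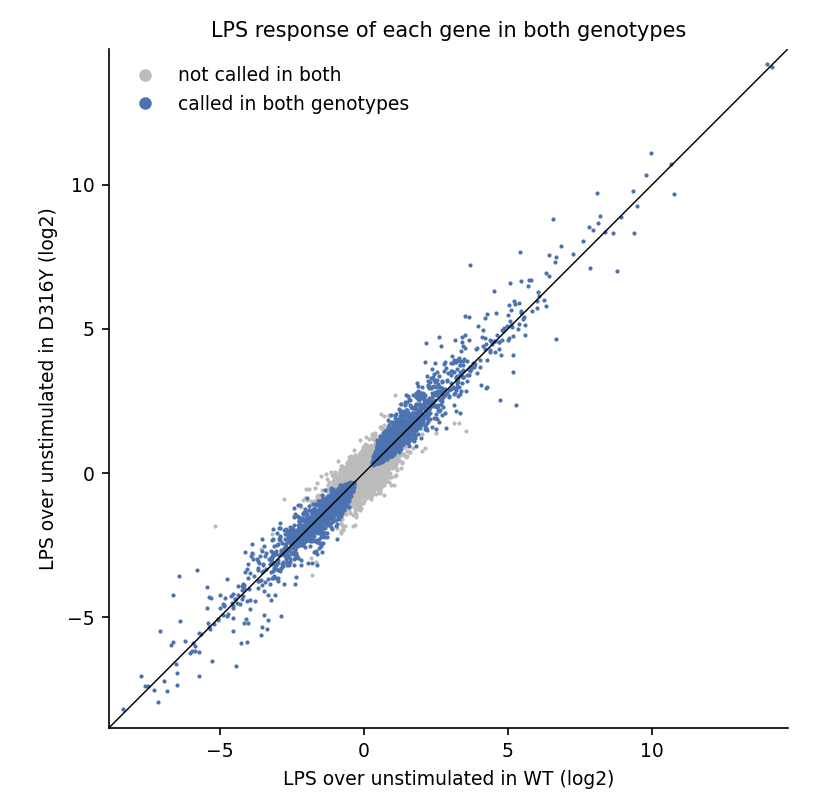
Log2 fold change with LPS in WT (x) against that in D316Y (y), 1 point per gene; blue points passed in both genotypes and the line is equality. Across 11540 genes Pearson's r was 0.959, and no gene passed in opposite directions.

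The LPS response was largely shared by the genotypes. Across 11540 genes Pearson's r of the log2 changes was 0.959, Spearman's rho 0.902 and the slope 0.991. In both genotypes 1798 genes rose, where 413 were expected by chance, and 1803 fell, where 416 were expected, and 0 passed in opposite directions by limma; the interaction above is the test of a difference.

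The authors' deposited test had 7 genes under adjusted p 0.05 without LPS and 10 with LPS. Before any alternative setting, 1 and 5 of these passed here. Without LPS they gave Rab4a -2.34, Ide -1.62, Dhcr7 1.30 and Zfp704 0.92, and the amino acid and one-carbon metabolism genes Phgdh -1.15, Asns -0.78 and Mthfd2 -0.64. With array weights, which called far more genes, each of these 7 passed here. With voom, Rab4a, Ide, Dhcr7 and Zfp704 passed. Without both unstimulated replicate 1 libraries, Rab4a, Ide, Dhcr7, Phgdh and Asns did. With LPS they gave Ifi208 4.58, Ide -1.66, Rab4a -2.82, G530011O06Rik -2.62 and Dhcr7 1.17. The rest of their genes with LPS, which did not pass here before any alternative setting, were Gm21748 -3.19, Gm21860 -3.18, Cnbd2 -1.39, Pnisr 0.82 and Selenbp2 1.21. The deposited value for Coq6 was 0.03 without LPS (adjusted p 0.925) and 0.01 with LPS (adjusted p 0.972).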

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

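The interaction test of the lists was set beforehand; the tests of explanations in this part, and the counts over other splits of the libraries, were chosen only after the results were seen.

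For 8 lists the interaction test found that the difference between D316Y and WT differed between resting and LPS-treated macrophages (camera adjusted p under 0.05), which is why they are given here. Type I interferon-stimulated genes had a median interaction of 0.68 on the log2 scale (positive in 38 of 38, adjusted p 1.27e-22; p = 0.0444 with an estimated correlation, adjusted p 0.817, so that the call was lost, as for each of the 8), from -0.60 without LPS to 0.09 with it. The integrated stress response had 0.27 (18 of 24, adjusted p 0.00417; p = 0.0976 with an estimated correlation), from -0.35 to -0.09, and 0.14 (adjusted p 0.116) without unstimulated D316Y replicate 2. Antigen presentation had 0.24 (21 of 24, adjusted p 0.000458; p = 0.149 with an estimated correlation), from -0.33 to -0.04; it was 0.07 without unstimulated WT replicate 1, 0.37 without unstimulated WT replicate 2 and 0.14 without unstimulated D316Y replicate 2. Inflammatory cytokines and chemokines had 0.29 (22 of 27, adjusted p 0.0117; p = 0.169 with an estimated correlation), from -0.23 to 0.15. Their adjusted p was above 0.05 without unstimulated WT replicate 2 (0.0618) or 3 (0.0602), WT LPS replicate 1 (median 0.10), unstimulated D316Y replicate 1 (0.18), or D316Y LPS replicate 1 or 2 (0.16 each), and the median was 0.49 and 0.47 without WT LPS replicate 2 and D316Y LPS replicate 3. Inflammatory effectors and NF-kB feedback genes had 0.21 (29 of 34, adjusted p 0.00417; p = 0.126 with an estimated correlation), from -0.25 to -0.01; without unstimulated WT replicate 1 the median was 0.14 (adjusted p 0.205), and without unstimulated D316Y replicate 1 the adjusted p was 0.0518.

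The other 3 lists were negative. Cytosolic ribosomal protein genes had -0.20 (46 of 48 negative, adjusted p 0.000153; p = 0.426 with an estimated correlation), from 0.24 without LPS to 0.05 with it. Their median was 0.08 without unstimulated WT replicate 1, -0.07 without WT LPS replicate 2 and -0.09 without unstimulated D316Y replicate 2, and between -0.43 and -0.32 without unstimulated D316Y replicate 1, unstimulated WT replicate 2 or 3, or WT LPS replicate 1. Respiratory complex I had -0.13 (31 of 36, adjusted p 0.0117; p = 0.369 with an estimated correlation), from 0.10 to -0.02, and complexes III to V had -0.13 (29 of 35, adjusted p 0.0230; p = 0.429 with an estimated correlation), from 0.12 to -0.02. Without unstimulated WT replicate 1 these medians were 0.0083 and 0.03, without WT LPS replicate 2 they were -0.03 and -0.04, and without unstimulated D316Y replicate 3 they were -0.06 and -0.10. Without D316Y LPS replicate 2 both lost the call (adjusted p 0.0542 and 0.0667), as complexes III to V did without unstimulated D316Y replicate 2 (0.0829), and without unstimulated D316Y replicate 1 they were -0.26 and -0.27. Without WT LPS replicate 1 they were -0.22 and -0.25, without unstimulated WT replicate 3 they were -0.20 and -0.23, and complexes III to V had -0.24 without unstimulated WT replicate 2.

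For the count of lists in the interaction, chance cannot be excluded. At least 8 lists were called in 68 of 100 splits of the libraries within the conditions. The highest count in another split was 16 lists. These 100 were the real split and others drawn at random. For genes the real count was 0, which every split must reach, so the splits say nothing about it. The highest count in another split, 124 genes, points to a structure of the samples. Splits that part all 3 unstimulated replicate pairs gave at most 1 gene. The split with 124 genes and another with 91 share 1 grouping of the unstimulated libraries, with both replicate 1 libraries on 1 side. Of the splits with both on 1 side 39 of 41 gave 0 genes, and of those with that grouping 4 of 6, so the grouping alone does not give the count.

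Interferon-stimulated genes stood lower in resting D316Y macrophages (median -0.60; p = 0.117 with an estimated correlation) and not in LPS-treated ones. A length or GC trend was argued against, since with it removed in the fit with the replicate block the median was -0.59 (adjusted p 7.82e-17). The replicate 1 libraries as the cause stay open: without both of them the median was -0.34 (adjusted p 1.27e-07), but the list means were 6.47 and 6.45 in WT and 5.68 and 6.53 in D316Y, so the rest lay in D316Y replicate 2. Variation between cultures unrelated to genotype stays open too: within the replicate pairs the list means differed by -1.07, -0.79 and 0.08, and a difference as large as the real -0.59 came from 3 of 10 splits of the 6 unstimulated libraries, the real one included, and from 2 of the 4 that part all 3 pairs (highest other 0.64 in size). With so few splits a share under 0.05 cannot be reached, so these and a lower basal interferon tone in D316Y cells, the biological explanation the design offers, cannot be told apart without more cultures.

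The unstimulated replicate 1 libraries of both genotypes stood apart from replicates 2 and 3, with mitochondrially encoded genes lower by medians of -2.16 in WT and -1.32 in D316Y and ribosomal protein genes by -0.81 and -0.63. Their deviations across 10177 genes were shared between the genotypes (Pearson's r 0.670, and 0.630 after a length and GC trend was removed). A GC trend was argued against as the shared cause, since its Spearman correlation with the deviation was 0.0206 in D316Y and 0.242 in WT. A length trend could account for a part: its correlation was 0.135 in WT and 0.141 in D316Y, between the bounds set for either answer, so it stays open. No biological explanation was tested, because nothing in the labels distinguishes replicate 1.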

How the results depend on the processing

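Coq6 was not called under any alternative, with log2 differences of -0.01 to 0.17 without LPS and -0.12 to 0.10 with LPS, and Ifi208 under LPS passed in 17 of 17 alternatives (4.51 to 4.98). Without LPS the count of genes, 1, was 0 with quantile normalization, with no filter, with a stricter filter and with plain eBayes, 122 with array weights, 6 with the replicate block, 4 with all 12 libraries in 1 fit and 0 to 1 when 1 library was left out. Among the alternatives chosen after seeing the data it was 4 with voom, 10 without both unstimulated replicate 1 libraries, 4 with the mitochondrial share as a covariate, and 2 and 4 with a length and GC trend removed, alone and with the block. With LPS the count, 5, was 1 with plain eBayes, 188 with array weights, 9 with voom and 2 to 22 when 1 library was left out. Array weights gave 7489 genes for LPS in WT. Camera with an estimated correlation called 0 lists in each of the 5 comparisons; fry called 0 in both genotype comparisons and the interaction, 22 for LPS in WT and 18 in D316Y. The lists called without LPS numbered 13 with the block, 17 without both replicate 1 libraries, 5 with the mitochondrial covariate and 5 to 15 when 1 library was left out; with LPS they numbered 2 to 12, in the interaction 5 to 11, and for LPS in D316Y 10 to 18, and 18 without both replicate 1 libraries. Among lists called with all libraries or in the reversing setting, medians that reversed when 1 library was left out had these ranges over the libraries. Without LPS they were -0.15 to 1.05 for mitochondrially encoded and -0.024 to 0.46 for ribosomal protein genes. With LPS they were -0.33 to 0.0025 for glycolysis, -0.011 to 0.26 for cytokine, -0.065 to 0.20 for ribosomal protein, -0.13 to 0.11 for complex I and -0.13 to 0.11 for complexes III to V. In the interaction they were -0.26 to 0.0083 for complex I, -0.27 to 0.033 for complexes III to V, -0.81 to 0.42 for mitochondrially encoded and -0.43 to 0.077 for ribosomal protein genes. Complex I and complexes III to V, not called without LPS with all libraries, also changed sign there over all alternatives (-0.04 to 0.21 and -0.06 to 0.23). With the mitochondrial covariate, which holds the reads of the mitochondrially encoded genes and so is no test of that list, the LPS medians reversed to -0.16 for mitochondrially encoded, 0.028 for tricarboxylic acid cycle, 0.14 for glycolysis, -0.19 for cytokine and -0.22 for ribosomal protein genes. For LPS in WT, ribosomal protein genes stood at -0.19 without both replicate 1 libraries, and dendritic cell markers, at a median of -0.18, were called upward by fry. The agreement of the genotype differences was 0.430 with a stricter filter. For these changes the cause was not tested. Leaving 1 library out keeps 2 in a group, whose spread is pooled with the others. The remaining values of single genes kept their side of the threshold in 1415 of 1455 cases without LPS, 1258 of 1301 with LPS, 1786 of 1786 in the interaction, 1935 of 1986 for LPS in WT and 1872 of 1929 in D316Y, and 0 of them changed sign where the gene passed with or without the change of setting; 23, 13 and 44 values that did not pass changed sign in the genotype comparisons without and with LPS and in the interaction. In the 4 comparisons other than the genotypes without LPS, a block on the replicate number added 2 lists with LPS (liver X receptor genes, -0.16, adjusted p 0.0371, and interferon-stimulated genes, 0.09, adjusted p 0.0474) and 1 in the interaction (mitochondrially encoded genes, -0.31, adjusted p 0.00783), and changed no other list call there; it gave 6 genes with LPS, 0 in the interaction, and 4186 and 4423 for LPS in WT and D316Y. Of the alternatives set beforehand, a pseudocount did not apply to log2 values and was not run. Depth limits genes with few reads: Nos2, at 6, 0 and 4 reads in resting WT, had an SE of 0.82 on the log2 scale.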

Other observations

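In this part the tests of explanations, the counts over splits and the choice of X-linked genes were made after the results were seen. The 4 Y-linked genes are the measured members of a list of sex-linked genes set beforehand. Printing all 4 of them was chosen after the results were seen.

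LPS also changed genes around coenzyme Q itself. Of 15 coenzyme Q biosynthesis genes 2 rose in WT and 3 in D316Y over all genes, and 2 and 2 adjusted over the list alone: the prenyltransferase Coq2 by 0.90 and 1.29, Coq10b, a coenzyme Q carrier, by 0.74 in WT, and the atypical kinases Coq8a and Coq8b by 0.77 and 0.43 in D316Y; the list was not called (medians 0.09 and 0.20, adjusted p 0.334 and 0.264). Of 14 quinone-linked dehydrogenases 5 rose and 2 fell in each genotype, over all genes and adjusted over the list alone (medians 0.14 and 0.14, adjusted p 0.187 and 0.233), and in D316Y the list was called without unstimulated replicate 1 (0.28, adjusted p 0.0427). The glycerol phosphate dehydrogenase Gpd2 rose by 2.73 and 2.51 and the succinate dehydrogenase subunits Sdhb by 0.98 and 0.91 and Sdhd by 0.91 and 0.89, the ferroptosis suppressor Aifm2 rose by 1.16 in each, and the proline dehydrogenase Prodh fell (-2.22 and -1.71). Antioxidant genes moved both ways (9 up and 4 down in WT, 9 and 5 in D316Y of 26; 10 and 4, and 10 and 6, adjusted over the list alone; adjusted p 0.159 and 0.233), with the superoxide dismutase Sod2 up by 4.45 and 4.46, the glutathione reductase Gsr by 2.05 and 1.74 and the heme oxygenase Hmox1 by 1.67 and 1.63. Ferritin, Fth1, rose by 2.16 and 2.25, to between 11.5% and 14.1% of all reads, and by 0.35 without passing under quantile normalization, which limits the highest values.

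Macrophage surface and lysosome genes were remodeled in part. Of 24 macrophage identity genes 6 rose and 9 fell in WT, and 6 and 8 in D316Y (adjusted p 0.305 and 0.383), with the lipid receptor Trem2 down (-2.84 and -2.81), the bridging ligand Gas6 down (-2.50 and -2.49) and the scavenger receptor Msr1 up by 2.30 in each. Of 30 lysosome genes 5 rose and 10 fell in WT and 4 and 9 in D316Y (adjusted p 0.201 and 0.319), with the proton pump subunit Atp6v0d2 at -4.19 and -3.86 and the acid lipase Lipa at -2.37 and -2.43. Among monocyte and dendritic cell markers, Ly6c2 rose by 7.25 and 7.58 and the homing receptor Ccr7 by 3.91 and 3.46, while Ccr2 fell (-1.71 and -1.72) and Cd24a fell (-4.53 and -5.48). Of the matrix genes, the protease Mmp14 rose by 5.58 and 5.12 and the urokinase Plau fell (-5.72 and -5.54). Lists with too few measured genes for a test had single values only. Without LPS the medians of D316Y over WT were -0.22 for B and plasma cell, -0.09 for stromal and -0.06 for erythroid and megakaryocyte markers. The T and NK cell value was that of Cd4 alone (-0.24). The mast cell value was that of Kit alone (-1.23), given above as a progenitor receptor. Their partners Lck and Hdc lay below the level for a test in both genotypes.

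Rab4a, Ide, Dhcr7 and G530011O06Rik differed between the genotypes by similar amounts with and without LPS, and Ifi208 did so in the same direction. For the 4 autosomal genes, a deletion or duplication spanning most neighbors within 1 Mb was argued against. With LPS the 62 neighbors had a median of 0.0513 in the direction of the called gene, with quartiles of -0.07 and 0.20. Of these, 38 went that way, 0 by at least 2-fold, with a range of -0.67 to 0.94. A median over 4 loci cannot exclude a small change that reaches few genes at a single locus, so that stays open. A segment around Coq6 kept from another strain was argued against as the source, with 0 of the genes called under LPS within 10 Mb of it, and a joint change of cholesterol synthesis was argued against for Dhcr7, with -0.17 as the median of the other 23 genes, 22 of them lower. For G530011O06Rik, with 4 tested neighbors at a median of 0.265 and quartiles of -0.38 and 0.88, a larger change at the end of the X chromosome may be involved and stays open. Other candidate explanations, such as a difference in genetic background between the mouse lines or their strain, were not tested, because the labels give no strain.

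The 4 tested neighbors of G530011O06Rik on the X chromosome went both ways in D316Y without passing: Mid1 lay at -1.57 without and -1.55 with LPS and Asmt at -0.56 and -0.66, while Gm15261 lay at 1.78 and 1.12 and Hccs at 0.06 and 0.13. The Y-linked genes Uty (0.65 and 0.48), Eif2s3y (0.70 and 0.64) and Kdm5d (0.34 and 0.88) were higher and Ddx3y lay at 0.26 and -0.03; 0 of these passed over all genes (limma), and adjusted over the list alone 0 did without LPS and 3 with LPS.

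In other splits of the same libraries, the real counts compare as follows. Each genotype or LPS comparison allows 10 splits, too few for a share under 0.05. The real split gave 1 gene without LPS and 5 with LPS, and 4328 and 4524 for LPS in WT and D316Y; the highest other split gave 0 genes in each, so that 1 of 10 splits was as large every time. For lists the real counts were 8, 7, 11 and 11 in that order, and the highest others 17, 13, 11 and 16; as many lists were called in 8, 8, 2 and 6 of the 10 splits. Without LPS the numbers paired the libraries for replicates 1 and 2 and not for replicate 3. WT replicate 3 correlated more with a D316Y library of another number (0.408) than with its own (0.203). There the splits that part all 3 pairs gave at most 11 lists in place of 8. The others, which place WT and D316Y libraries of 1 number in the same group, gave up to 17.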
